A study of Homo sapiens with 4 samples.

How the data were processed

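RNA sequencing was analysed from 4 libraries of ARP-1, a human multiple myeloma cell line. The labels give 2 libraries of wild-type cells (WT, replicates 1 and 2) and 2 of cells resistant to carfilzomib (CfzR, replicates 1 and 2), an inhibitor of the proteasome. Per the labels' protocols, RNA was extracted with TRIzol and libraries followed an mRNA protocol. STAR and Cufflinks are named per the submitters' processing notes; their versions, the genome build, the annotation and the strandedness of counting are not given in the sources used here.

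The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled to library size), with 15201 Ensembl gene IDs and 1 column per library. The unit was read from the tool named in the labels, the ID column name in the file header and the decimal values. The lowest row mean over the 4 libraries was 0.500 FPKM, and 306 genes had a value of 0 in at least 1 library. The columns of the resistant cells carry the drug's abbreviation. The remaining columns carry a short name for a control, which was assigned to WT because WT is the only other group. The FPKM values hold no counts and no shared step of 1 read was found, so sequencing depth is unknown and no counting error is given.

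Gene symbols were matched by ID for 15027 of the 15201 genes, and 174 kept their ID. Positions are those of GENCODE release 29 (GRCh38), matched by gene ID for 14496 genes. They are not coordinates given by the authors. Transcript length and GC share came from the longest transcript of the same release.

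Values were transformed to log2(FPKM + 1). Genes with a mean of at least 1 FPKM over the 4 libraries were kept, which left 13411. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend), with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Log2 fold changes are on the log2(FPKM + 1) scale, which understates changes of genes with low values. Plain folds are ratios of mean FPKM. Tests were two-sided. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. With 2 libraries per group there are 3 ways to divide the 4 libraries, too few for a permutation test to reach the threshold.

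A total of 44 gene lists was written from textbook knowledge, and the 39 with at least 5 measured members were tested with camera (limma) at a preset correlation between genes of 0.01. Camera with an estimated correlation and fry were run beside it. The p-values printed below with an estimated correlation are unadjusted. With that test the smallest adjusted p over the 39 lists was 0.666. Members past the threshold were counted over all genes tested and adjusted over the list alone. The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Under the rule, the text names the 8 genes with the largest positive and the 8 with the largest negative log2 fold change, among genes past the threshold with a group mean of at least 5 FPKM and groups that did not overlap. It also names up to 4 members past the threshold per list, and a fixed set of genes of cholesterol and lipid metabolism, proteasome, stress, apoptosis and myeloma identity. Any other gene in the text was chosen after its values were seen. Genes of these lists and of the fixed set without a value are not analysed here, and some genes of the fixed set are not reported here.

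The alternatives were pseudocounts of 0.1 and 5, no filter, a filter at 5 FPKM, scaling of the values by trimmed means of M-values (TMM, computed directly in R), quantile normalization, no mean-variance trend, the replicate number as a block, leaving out each library, stricter thresholds and the other list tests. A correction for transcript length and GC share was added after seeing the data. In each library, the deviation from the gene's mean was regressed on splines with 4 degrees of freedom of log2 length and of GC share, and the fitted trend was removed. It covered 12896 of the tested genes (96.2%).

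The procedure was tested on simulated data for this comparison, with 13411 genes of which 200 were changed. At a log2 change of 1, 4.41% of changed genes were recovered, at 2 it was 78.8% and at 4 it was 98.5%, with 6.25% false calls among all calls. A list shifted by 0.5 was recovered and 0 of 38 other lists were called. The simulated genes varied independently, so this cannot vouch for list calls where genes move together. Estimated correlations between genes in the data were 0.734 for ribosomal proteins and 0.751 for mitochondrially encoded transcripts. The length and GC correction, run on 12896 genes, brought a planted length trend with a correlation of 0.398 across genes to 0. This outcome was fixed in advance, since the planted trend lay within the fitted splines. It shows that the step ran as written, not that it removes other trends or keeps real changes. Windows of 10 neighbouring genes were compared with 1000 shuffles of gene order. In a simulation on 12877 genes, a planted segment of 10 genes raised by 1.5 was found at its place. This too shows only that the step ran, since the highest window median in the 1000 shuffles was 0.86. Window scans used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots used matplotlib 3.10.9.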

Results

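Gene expression was measured in wild-type ARP-1 cells (WT, n = 2 libraries) and in ARP-1 cells resistant to carfilzomib (CfzR, n = 2). The median FPKM over 15201 genes was 7.50 and 7.74 in WT replicates 1 and 2, and 7.75 and 7.73 in CfzR replicates 1 and 2. The sums of FPKM were 918617, 955284, 673265 and 877849 in the same order. Pearson correlations of log2 values across genes, which are not independent replicates, were 0.983 between the WT libraries and 0.968 between the CfzR libraries. They lay between 0.947 and 0.975 across groups, so the CfzR pair was no closer than WT replicate 2 and CfzR replicate 2 (0.973) or WT replicate 1 and CfzR replicate 2 (0.975). The same immunoglobulin constant genes led in every library. IGKC, the kappa light chain, stood at 13828 and 9844 FPKM in WT and 13684 and 17706 in CfzR.

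The comparison asks how the transcriptome of resistant cells differs from that of the parental line. ABCB1, which encodes the drug efflux pump P-glycoprotein, rose from 0.953 ± 0.455 FPKM in WT to 248 ± 28.1 in CfzR (SD, n = 2 each), a 261-fold difference (log2 fold change 7.01, SE 0.23, limma adjusted p = 5.15e-05). S100A4, a calcium-binding protein linked to cell motility, fell from 224 ± 21.9 to 0.602 ± 0.263 FPKM, a level 372-fold lower in CfzR (log2 fold change -7.14, SE 0.21, adjusted p = 5.06e-05). CST3, the secreted protease inhibitor cystatin C, stood at 71.6 and 70.5 FPKM in WT and was listed at 0 in both CfzR libraries (adjusted p = 5.06e-05). SLAMF7, a plasma cell surface receptor and the target of elotuzumab, rose 84.8-fold, from 0.240 ± 0.0591 to 20.4 ± 2.42 FPKM (adjusted p = 5.25e-04). The fixed lists of cholesterol, lipid and proteasome genes held no member past the threshold. In the simulation, 4.41% of genes with a log2 change of 1 were recovered, so this does not show that these genes were unchanged.

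**Figure D1:**
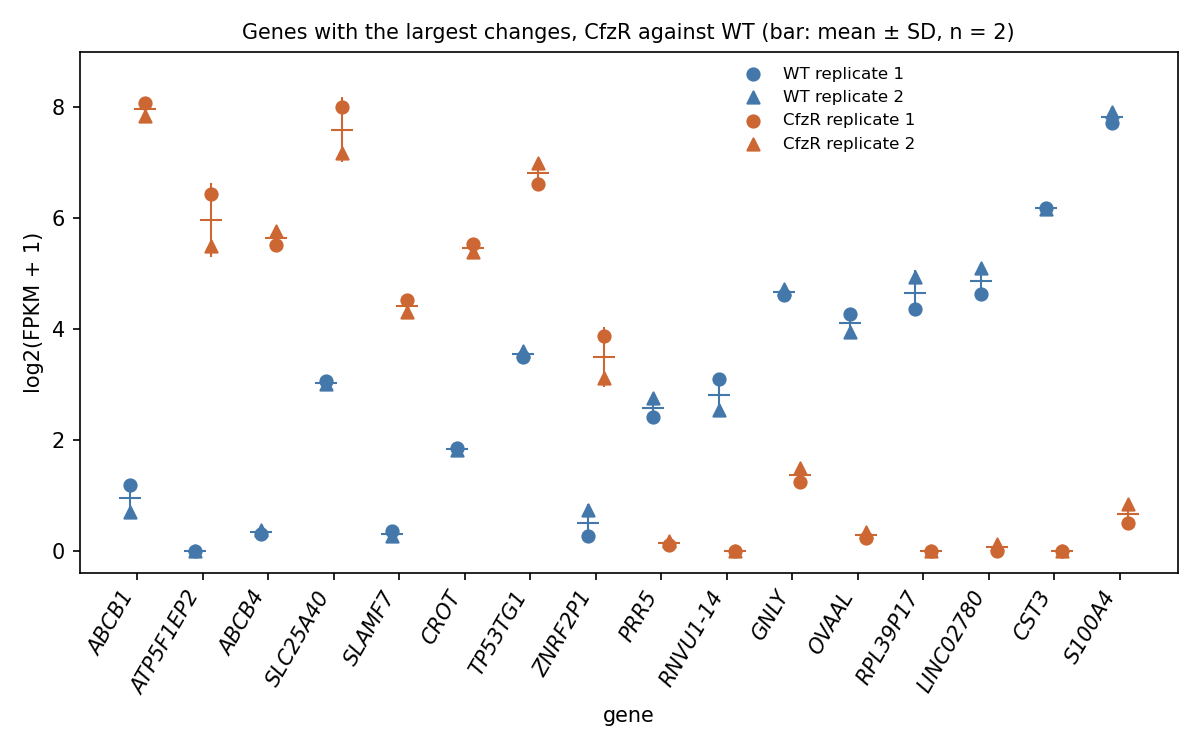
Log2(FPKM + 1) of the 16 genes with the largest changes, 8 in each direction, chosen by the fixed rule. Points are single libraries (circle, replicate 1; triangle, replicate 2), horizontal bars are means and vertical lines SD (n = 2). ABCB1 lay near 8 in both CfzR libraries, and CST3 was listed at 0 in both.

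Of 13411 genes tested, 47 passed the threshold with limma. Among them 33 were higher in CfzR and 14 lower. At an unadjusted p under 0.05 there were 1492 genes, where chance alone would give 671. The groups did not overlap for 5999 genes (44.7%, against 33.3% by chance). They did not overlap for all 47 genes past the threshold either, which follows from the call, since overlapping groups of this size cannot reach it. The smallest absolute log2 fold change among the 47 was 1.45. Leaving out 1 library leaves a lone library in its group. Error in those fits comes from the other group and from values pooled over genes, so counts passing there cannot show dependence on a library. Adjusted p given below with a library left out carry the same limit. Log2 fold changes with 1 library left out ran from 6.77 to 7.25 for ABCB1, 1.998 to 2.075 for RGS1 and 2.62 to 3.38 for ZNRF2P1. With a replicate block the excess of higher genes turned (487 higher and 755 lower). That fit leaves 1 residual degree of freedom per gene, so its p-values rest more on values pooled over genes.

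Of the 8 genes with the largest positive log2 fold changes under the fixed rule, 5 lay within 1 Mb on chromosome 7. ABCB1 (ENSG00000085563) spans 87503633 to 87713323 on the minus strand of GRCh38, in band 7q21. Its neighbour ABCB4, a phospholipid transporter of the bile canaliculus, rose from 0.257 ± 0.0430 to 49.0 ± 6.0 FPKM (191-fold, adjusted p = 1.13e-04). SLC25A40, a mitochondrial carrier, rose 27.8-fold from 7.18 ± 0.269 to 199.5 ± 79.6 FPKM (adjusted p = 0.00118). CROT, which acts in peroxisomal fatty acid oxidation, rose 16.9-fold to 43.0 ± 2.77 FPKM (adjusted p = 5.25e-04). The noncoding RNA TP53TG1 rose 10.4-fold to 112 ± 20.3 FPKM (adjusted p = 0.00124). The 10 consecutive tested genes from ELAPOR2 to SLC25A40 (86876906 to 87876357) had a median log2 fold change of 2.69, and 7 of them rose. Of the other 3, ELAPOR2 (log2 fold change 1.43) and DMTF1 (1.20) did not pass, and ENSG00000273623, between TP53TG1 and CROT, was listed at 0 in 3 libraries and stood at 115 FPKM in WT replicate 2 (log2 fold change -3.43, adjusted p = 0.527). DMTF1-AS1 and TMEM243, named after their values were seen, completed the 7, with log2 fold changes of 2.12 and 1.58. Their adjusted p was 0.178 and 0.159 without CfzR replicate 1, and 0.0875 and 0.0838 without CfzR replicate 2. The antisense transcript DMTF1-AS1 is uncertain, since the use of strand is not known, and so is ABCB4 as a paralogue of ABCB1. Outside the window, GNAI1 rose (log2 fold change 2.50, adjusted p = 0.0151; 0.159 without CfzR replicate 1 and 0.0822 without CfzR replicate 2). SEMA3D, DBF4 and STEAP1 did not pass, with log2 fold changes of 1.95, 1.09 and 0.95, and SRI, between the last pair, had 0.01. These neighbours were named after their values were seen. In all, 11 genes of chromosome 7 rose.

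**Figure D2:**
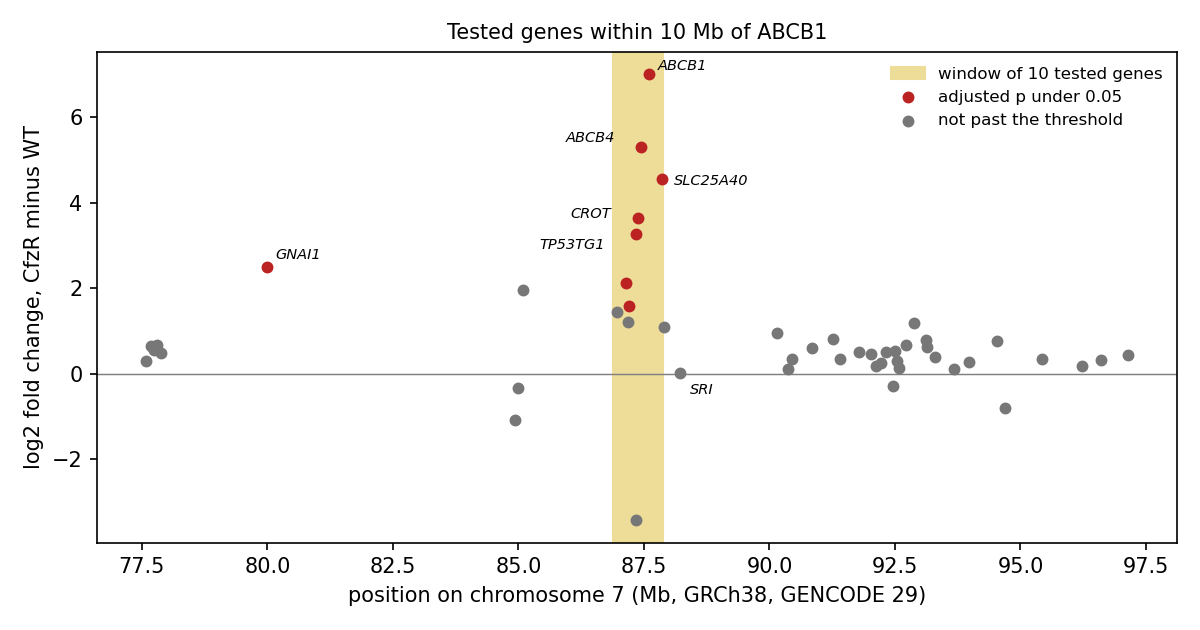
Log2 fold change (CfzR minus WT) of tested genes against their position on chromosome 7 within 10 Mb of ABCB1, in Mb of GRCh38. Red points passed the threshold on the limma adjusted p, and the shaded window of 10 genes holds 7 of them.

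Other genes of the fixed rule changed elsewhere in the genome. S100A4 lies on chromosome 1 (153543613 to 153550136), as does SLAMF7 (160739057 to 160754821), and CST3 on chromosome 20 (23626706 to 23638473). GNLY, a cytolytic granule protein, fell from 24.3 ± 1.28 to 1.58 ± 0.318 FPKM (adjusted p = 0.00113). The long noncoding RNA OVAAL fell from 16.3 ± 2.75 to 0.216 ± 0.0661 FPKM (adjusted p = 9.30e-04). LINC02780 stood at 23.7 and 33.1 FPKM in WT and was listed at 0 and 0.0917 in CfzR (adjusted p = 5.25e-04). PRR5, a subunit of the mTORC2 kinase complex, fell from 5.02 ± 0.987 to 0.102 ± 0.0387 FPKM (adjusted p = 0.0176), and its adjusted p was 0.159 without CfzR replicate 1 and 0.0822 without CfzR replicate 2. The spliceosomal RNA variant RNVU1-14 stood at 7.52 and 4.77 FPKM in WT and was listed at 0 in both CfzR libraries (adjusted p = 0.0151). As a small nuclear RNA in libraries made by an mRNA protocol, its level is uncertain. Pseudogenes share sequence with their parent genes and are uncertain: ATP5F1EP2 was listed at 0 in both WT libraries and stood at 85.6 and 44.1 FPKM in CfzR, and RPL39P17 stood at 19.6 and 29.7 FPKM in WT and at 0 in CfzR. ZNRF2P1, also a pseudogene, stood at 0.430 ± 0.331 in WT and 10.7 ± 4.26 FPKM in CfzR (adjusted p = 0.0206). ZNRF2P1 and RNVU1-14 did not pass without CfzR replicate 1 (both 0.171) or without CfzR replicate 2 (0.0822 and 0.0838). After the length and GC correction their adjusted p was 0.0751 and 0.0888, as the SE grew from 0.32 to 0.46 and from 0.28 to 0.37, with log2 fold changes of 3.31 and -2.49 against 2.998 and -2.81 before.

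Among multidrug ABC transporters, 2 of 7 measured members rose, ABCB1 and ABCB4, and 5 did not pass the threshold, with the same 2 adjusted over the list alone. The list's median log2 fold change was 0.01 against a mean of 1.74. It was higher by camera (adjusted p = 0.0139), with p = 0.169 with an estimated correlation, and the adjusted p was 0.0642 without CfzR replicate 1 and 0.132 without CfzR replicate 2.

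Of 23 plasma cell genes measured, SLAMF7 and CAV1 rose and 21 did not pass. Adjusted over the list alone, 3 were higher and 2 lower. CAV1, a caveolar coat protein, rose from 4.18 ± 0.507 to 28.9 ± 5.80 FPKM (adjusted p = 0.00815; 0.0919 without CfzR replicate 1). LY9, CXCR4 and GPRC5D, named after their values were seen, passed only over the list alone, with mean FPKM of 0.768, 29.15 and 86.6 in WT and 4.13, 14.1 and 43.2 in CfzR. SDC1, the CD138 antigen, stood at 197 ± 10.8 in WT and 242 ± 41.5 FPKM in CfzR (adjusted p = 0.661). TNFRSF17, the BCMA receptor, stood at 347 ± 49.5 and 234 ± 57.5 FPKM (adjusted p = 0.495), and CD38 at 14.9 ± 1.88 and 16.5 ± 6.37 (adjusted p = 0.913). The list's camera adjusted p was 0.192. It passed without WT replicate 1 (0.0268), without WT replicate 2 (0.0289), under quantile normalization (0.0101) and with a replicate block, in a range of 0.0101 to 0.838 over its alternatives.

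NF-kB targets were higher in CfzR, with 9 of 11 members positive and a median log2 fold change of 0.45 (camera adjusted p = 4.63e-04; p = 0.0891 with an estimated correlation; adjusted p = 0.0978 without CfzR replicate 2). RGS1, a regulator of G protein signalling, rose from 3.37 ± 0.165 to 16.9 ± 0.348 FPKM (adjusted p = 0.0125; 0.112 without CfzR replicate 1 and 0.0822 without CfzR replicate 2). The other 10 did not pass over all genes. Adjusted over the list alone 4 were higher: RGS1, BIRC3, TNFAIP3 and NFKBIA.

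None of 24 apoptosis regulators passed over all genes, and adjusted over the list alone 3 were higher and 1 lower (6 at an unadjusted p under 0.05, camera adjusted p = 0.170). BCL2, which blocks mitochondrial apoptosis, stood at 4.72 ± 0.0714 in WT and 13.1 ± 3.68 FPKM in CfzR (log2 fold change 1.28, SE 0.24, adjusted p = 0.118; 0.0131 adjusted over the list alone). MCL1, a related survival factor, stood at 236 ± 18.5 and 281 ± 67.7 FPKM (adjusted p = 0.744). MYC stood at 297 ± 42.9 and 287 ± 28.1 FPKM (log2 fold change -0.04, adjusted p = 0.956). Of 22 myeloma oncogenes and cyclins, 0 passed over all genes and 1 was higher adjusted over the list alone (4 at an unadjusted p under 0.05, camera adjusted p = 0.170).

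Cholesterol and lipid lists follow a theme that the submitters report for these cells, so they are not independent evidence. Counts of 0 below do not exclude changes, since most simulated genes with a log2 change of 1 were missed. Of 20 cholesterol biosynthesis genes, 0 passed over all genes tested by limma and 0 adjusted over the list alone, and 2 had an unadjusted p under 0.05. Of these 15 had negative log2 fold changes, with a median of -0.23 (camera p = 0.0373, adjusted p = 0.132; p = 0.159 with an estimated correlation). HMGCS1 and SQLE, enzymes of the pathway, had log2 fold changes of 0.31 and -0.37 (adjusted p = 0.601 and 0.549). After the length and GC correction the list's adjusted p was 0.0472, in a range of 0.0472 to 0.666 over its alternatives.

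Of 17 genes of sterol uptake and SREBP regulation, 0 passed in limma, over all genes or adjusted over the list alone, with 2 at an unadjusted p under 0.05 (camera adjusted p = 0.710). The transcription factors SREBF1 and SREBF2 had log2 fold changes of -0.06 and 0.04, and their feedback regulator INSIG1 one of -0.44 (SE 0.21, adjusted p = 0.493). Of 14 genes of cholesterol efflux, esterification and LXR control, 0 passed either way and 2 had an unadjusted p under 0.05 (camera adjusted p = 0.710), with the efflux pump ABCA1 at a log2 fold change of 0.45 (adjusted p = 0.543). Of 20 genes of fatty acid synthesis and desaturation, 0 passed over all genes and 1, the elongase ELOVL6, was higher adjusted over the list alone (log2 fold change 0.92; camera adjusted p = 0.710). FASN stood at 46.3 ± 16.6 and 46.1 ± 1.79 FPKM, and the desaturase SCD at 111 ± 0.878 and 70.7 ± 19.4 (log2 fold change -0.67, adjusted p = 0.389). No member passed either way among 16 genes of triacylglycerol and lipid droplets, 21 of phospholipid synthesis, 25 of sphingolipid metabolism and 23 of fatty acid oxidation, with camera adjusted p of 0.901, 0.920, 0.217 and 0.605, and with 0, 2, 1 and 2 members at an unadjusted p under 0.05. CROT, which rose, is in none of these lists.

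The drug's target showed no member past the threshold, which would miss most log2 changes of 1, as the simulation showed. Of 13 genes of the 20S core proteasome, 0 passed in limma over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05 (median log2 fold change -0.13, camera adjusted p = 0.710). PSMB5, the subunit that carfilzomib binds, stood at 119 ± 16.8 in WT and 97.0 ± 28.4 FPKM in CfzR (log2 fold change -0.32, SE 0.27, adjusted p = 0.659). POMP, the proteasome maturation protein, had a log2 fold change of 0.23 (adjusted p = 0.666). PSMB8 is not analysed here. The counts were likewise 0 of 18 for the 19S particle, 0 of 13 for the immunoproteasome, activators and assembly factors, and 0 of 25 for ubiquitin and deubiquitinating enzymes, with camera adjusted p of 0.920, 0.901 and 0.710. At an unadjusted p under 0.05 there were 2, 0 and 1. For the 19S list and the assembly list the mean was below 0 (-0.03 and -0.01) while the median and the camera direction were positive.

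Genes of the unfolded protein response were higher as a list, with no single member past the threshold. Of 31 endoplasmic reticulum chaperones and targets of IRE1 and ATF6, 25 were positive and 5 had an unadjusted p under 0.05, with medians of 0.28 and 0.30 above WT in CfzR replicates 1 and 2 (camera adjusted p = 0.00510; p = 0.0603 with an estimated correlation; adjusted p = 0.107 without WT replicate 1 and 0.0790 without CfzR replicate 2). HSPA5, the chaperone BiP, stood at 63.9 ± 5.52 and 104 ± 14.5 FPKM (log2 fold change 0.69, SE 0.21, adjusted p = 0.306). XBP1, the factor spliced by IRE1, stood at 1019 ± 93.1 and 834 ± 48.4 FPKM (log2 fold change -0.29, adjusted p = 0.720). Under quantile normalization its log2 fold change was 0.0828. Of 31 ATF4 and amino acid stress genes, 26 were positive, 0 passed either way and 6 had an unadjusted p under 0.05 (camera adjusted p = 0.00401; p = 0.0806 with an estimated correlation; adjusted p = 0.0607 without WT replicate 2 and 0.0642 without CfzR replicate 1).

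Of 29 glycolysis and hypoxia genes, 22 were positive and 0 passed over all genes, and 1, ENO2, was higher adjusted over the list alone (3 at an unadjusted p under 0.05; camera adjusted p = 0.0139; p = 0.0758 with an estimated correlation). This call was lost without WT replicate 1 (0.107), WT replicate 2 (0.0702) or CfzR replicate 2 (0.0978), and with a replicate block. Of 20 cytosolic heat shock genes, 21 NRF2 targets and 30 autophagy and lysosome genes, 0 passed either way, with camera adjusted p of 0.603, 0.217 and 0.920 and with 2, 3 and 2 members at an unadjusted p under 0.05. The autophagy list had a negative median (-0.03) and a positive camera direction. Its member SQSTM1, an autophagy receptor, stood at 1.56 ± 0.257 and 1.83 ± 0.108 FPKM. Among 21 ferroptosis regulators 0 passed over all genes and 2 were higher adjusted over the list alone, SLC7A11 and GCH1 (6 at an unadjusted p under 0.05, camera adjusted p = 0.920, positive against a median of -0.02). Of 23 genes of serine, one-carbon and glutathione metabolism, 0 passed either way and 3 had an unadjusted p under 0.05 (camera adjusted p = 0.114).

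Ribosomal protein genes were lower as a list. All 49 measured members had negative log2 fold changes, and 0 passed in limma over all genes, adjusted over the list alone or at an unadjusted p under 0.05 (median -0.36, camera adjusted p = 3.43e-06; p = 0.392 with an estimated correlation). Their medians relative to WT were -0.60 in CfzR replicate 1 and -0.10 in CfzR replicate 2, and under quantile normalization the list turned positive (adjusted p = 0.823). CfzR replicate 1 also stood apart by transcript length: its difference from CfzR replicate 2 correlated with length across genes (Spearman 0.466) and inversely with GC share (-0.350), against 0.146 and 0.0793 for the WT pair. Nuclear genes of oxidative phosphorylation showed the same split, with medians of -0.48 and 0.06 (0 of 44 passed either way, 2 at an unadjusted p under 0.05, camera adjusted p = 0.0566). Without CfzR replicate 2 the adjusted p was 1.56e-04, and the direction turned without CfzR replicate 1 (0.678) and under quantile normalization.

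All 15 mitochondrially encoded transcripts had negative log2 fold changes, 0 passed either way and 1 had an unadjusted p under 0.05 (median -0.60, camera adjusted p = 4.63e-04; p = 0.323 with an estimated correlation). Their share of all FPKM was 8.44% in WT replicate 1, 4.28% in WT replicate 2, 4.18% in CfzR replicate 1 and 4.85% in CfzR replicate 2. Without WT replicate 1 the list's adjusted p was 0.695, and under quantile normalization it was 0.158. Of 28 genes of the tricarboxylic acid cycle and pyruvate entry, 0 passed in limma either way or at an unadjusted p under 0.05 (camera adjusted p = 0.901).

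**Figure D3:**
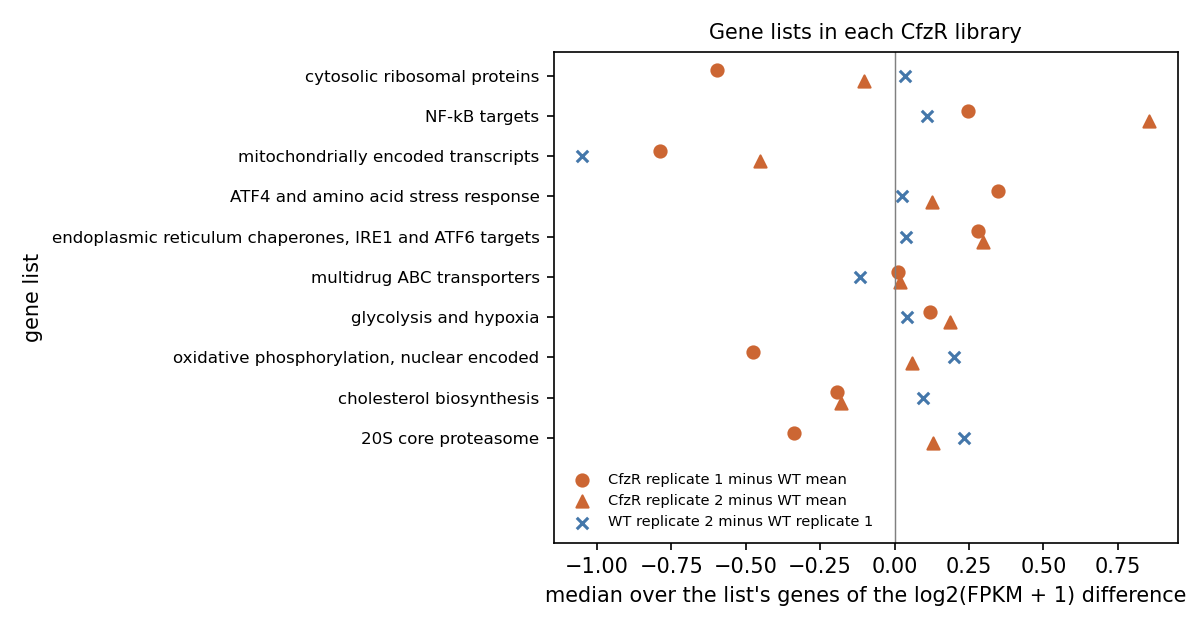
Median over each gene list of the log2(FPKM + 1) difference from the WT mean, for CfzR replicate 1 (circles) and replicate 2 (triangles), with the difference between the WT libraries as crosses. Ribosomal proteins lay at -0.60 and -0.10 (positive as a list under quantile normalization), and mitochondrial transcripts differed most between the WT libraries.

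Cell cycle and immune lists held few changes. Of 39 G1/S and DNA replication genes and 40 G2/M genes, 0 passed either way (camera adjusted p = 0.0730 and 0.493; 3 and 0 at an unadjusted p under 0.05), and the first list reached 0.0384 without CfzR replicate 1. It was also past the threshold with a pseudocount of 5 (0.0249), a filter at 5 FPKM (0.0351), quantile normalization (0.00720) and the length and GC correction (0.0380), in a range of 0.00720 to 0.666 over its alternatives. The counts were also 0 of 19 for p53 targets (0.502) and 0 of 13 for replication-dependent histones (0.478). Of 11 interferon response genes 0 passed and 2 were higher adjusted over the list alone (camera adjusted p = 0.171). Of 10 genes of MHC class I presentation 0 passed, with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.920). Of 19 adhesion genes 0 passed, with 2 higher and 1 lower adjusted over the list alone (0.572), and of 24 cytokine and growth factor receptors 0 passed, with 2 lower (0.667). At an unadjusted p under 0.05 there were 2 p53 targets, 3 histones, 3 interferon response genes, 5 of MHC class I presentation, 5 of adhesion and 4 receptors.

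Markers of other cell types were counted only where they had a value and passed the filter, and a marker without a value is not analysed here rather than shown to be absent. Of 22 T and NK cell markers 3 were measured, of which GNLY fell and 2 did not pass; adjusted over the list alone TRAC was higher (12.9 ± 4.25 in WT and 28.4 ± 1.46 FPKM in CfzR). Of 5 epithelial markers 0 passed, with CLDN3 higher and KRT18 lower adjusted over the list alone (camera adjusted p = 0.710), and of 5 B cell markers 0 passed either way (0.955; negative in camera and in the mean, -0.02, against a median of 0.06). Of 3 myeloid markers 0 passed over all genes and ITGAX was lower adjusted over the list alone. Of 2 stromal markers 0 passed, with FN1 higher adjusted over the list alone, and 0 passed among 2 erythroid and 4 MHC class II genes.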

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

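Among the tests here, the length and GC correction was chosen after seeing the data. Of 33 named genes tested under every setting, 27 kept their direction and their side of the threshold under all planned pseudocounts, filters, scalings, the fit without a trend and the block, as did 22 of 37 gene lists. DESeq2 was not run, since it needs counts. Depth is unknown, so no limit from counting can be given. Where values changed, the cause was not tested, except that fewer genes or libraries entered some fits.

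Against 47 genes (33 higher, 14 lower), a filter at 5 FPKM gave 27 (18 and 9) from 9014 genes tested, and 25 of the 28 that remained in the test passed. An adjusted p under 0.01 left 15 (9 and 6). Leaving out 1 library, where the lone sample is assumed to vary like the other group, gave 16 to 260 genes, 8 to 118 higher and 7 to 142 lower. Lists past the threshold numbered 7, or 4 to 6 with 1 library left out, 0 with camera at an estimated correlation and 0 with fry (smallest adjusted p 0.0878), though fry's mixed test called 13. With the replicate block 1242 genes passed, 487 higher and 755 lower, all 47 among them, and BCL2, SCD and HSPA5 passed (limma adjusted p = 3.24e-06, 0.0320 and 0.0231). The block leaves 1 residual degree of freedom per gene, so these p-values rest more on values pooled over genes. The log2 fold change of BCL2 was 1.28 with and without the block. Same-numbered libraries deviated together with a correlation of 0.252, but with 2 pairs and no label to that effect the numbers are not shown to pair samples. The cholesterol biosynthesis list passed after the length and GC correction (adjusted p = 0.0472), its range over alternatives being 0.0472 to 0.666.

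Some lists changed sides of the threshold. The plasma cell list passed with the replicate block (0.0110), where the glycolysis and hypoxia list no longer did (0.0510). Under quantile normalization the myeloma oncogene and cyclin list (0.0337) and the serine and one-carbon list (0.0177) passed, the second also with a pseudocount of 5 (0.0403). Oxidative phosphorylation passed with that pseudocount (0.0339) and with no filter (0.0387). Over their alternatives, adjusted p ran from 0.0101 to 0.838 for plasma cells, 3.01e-05 to 0.666 for glycolysis, 0.0337 to 0.666 for myeloma oncogenes, 0.0177 to 0.666 for serine and 1.56e-04 to 0.924 for oxidative phosphorylation.

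Directions turned for several genes and lists, ribosomal proteins and oxidative phosphorylation among them. Under quantile normalization log2 fold changes were 0.21 for MYC, 0.0828 for XBP1 and 0.19 for SREBF1. After the length and GC correction they were 0.0494 for MYC, 0.0436 for SREBF1 and -0.0222 for CD38. With 1 library left out they ran from -0.0546 to 0.13 for SREBF2, -0.19 to 0.11 for MYC, -0.33 to 0.40 for FASN, -0.29 to 0.47 for CD38, -0.0153 to 0.48 for MCL1 and -0.17 to 0.0602 for SREBF1.

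Lists that turned under quantile normalization had adjusted p of 0.823 (ribosomal proteins), 0.414 (20S proteasome), 0.689 (heat shock), 0.645 (MHC class I), 0.49997 (oxidative phosphorylation) and 0.464 (tricarboxylic acid cycle). With no filter these were 0.990 (autophagy) and 0.719 (B cell markers), and at 5 FPKM 0.992 (phospholipids), 0.925 (MHC class I) and 0.952 (tricarboxylic acid cycle). With the replicate block they were 0.991 (phospholipids and B cell markers) and 0.994 (19S proteasome), with fry 0.919 (19S proteasome and autophagy), and after the length and GC correction 0.917 (19S proteasome), 0.849 (ubiquitin enzymes) and 0.937 (B cell markers). With 1 library left out, adjusted p ran from 0.655 to 0.984 for phospholipids, 0.709 to 0.997 for the 19S proteasome, 0.775 to 0.919 for B cell markers, 0.238 to 0.984 for fatty acid synthesis, 0.182 to 0.984 for the 20S proteasome, 0.709 to 0.990 for the tricarboxylic acid cycle, 0.361 to 0.984 for sterol uptake, 0.872 to 0.984 for MHC class I, 1.56e-04 to 0.678 for oxidative phosphorylation and 0.0685 to 0.988 for cytokine receptors.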

Other observations

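The window, paralogue, immunoglobulin, replicate and gene pair tests and the length and GC correction were chosen only after the results they bear on were seen. Other genes past the threshold were named after their values were seen. LGALS9, the lectin galectin-9, rose from 6.0 ± 1.22 to 19.4 ± 1.45 FPKM (limma adjusted p = 0.0489), and IFI16, a DNA sensor induced by interferon, from 3.68 ± 0.216 to 11.8 ± 0.229 (adjusted p = 0.0457; 0.0620 after the length and GC correction, with a log2 fold change of 1.29 against 1.45 before and an SE of 0.17 against 0.20). NAPSA, the aspartic protease napsin A, fell from 179 ± 44.9 to 36.8 ± 13.3 FPKM (adjusted p = 0.0474; 0.0568 after that correction, with a log2 fold change of -2.20 against -2.27 and an SE of 0.28 against 0.31). GRAMD1A, a carrier of cholesterol from the plasma membrane, fell from 43.9 ± 0.0640 to 14.2 ± 0.634 FPKM (adjusted p = 0.0273), and it is in none of the fixed lists. The metallothionein MT1F stood at 3.96 and 2.94 FPKM in WT and at 0.0889 and 0 in CfzR (adjusted p = 0.0342; 0.0845 after that correction, with a log2 fold change of -1.89 against -2.08 and an SE of 0.27 against 0.26). These 5 genes had adjusted p of 0.159 to 0.197 without CfzR replicate 1 and 0.0822 to 0.0875 without CfzR replicate 2. The surface proteins CD82 and CD81, both tetraspanins, had log2 fold changes of 1.63 and -1.70 (adjusted p = 0.0919 and 0.118), so neither passed over all genes.

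Windows of 10 neighbouring genes beyond 7q21 also stood apart. The highest median in 1000 shuffles of gene order was 0.86 and the lowest -0.82. Shuffles also break trends of length and GC share that neighbours may have in common. The windows named next were not rechecked after the length and GC correction. A window on chromosome 7 from 64141538 to 65508944, with the zinc finger genes ZNF107, ZNF138, ZNF273 and ZNF92, had a median log2 fold change of 1.02, and none of these 4 genes passed the threshold. A window on chromosome 2 over IGKC and kappa variable segments had a median of 1.04, but the segments share sequence and are uncertain. The lowest window, on chromosome 1, had a median of -0.91 and holds copies of mitochondrial genes. MTND1P23, for example, stood at 394 and 315 FPKM in WT replicates 1 and 2 and at 91.1 and 236 in CfzR (adjusted p = 0.361). Mitochondrial transcripts held 8.44% of all FPKM in WT replicate 1 against 4.28%, 4.18% and 4.85% in the other libraries, and their list had an adjusted p of 0.695 without WT replicate 1. Among 24 genes that rose more than 10 Mb from ABCB1, 3 pairs lay within 1 Mb of each other: WASF1 with SLC16A10, GAS2 with SVIP, and ZNRF2P1 with ENSG00000273014. Random sets, which were not matched for expression, had a mean of 0.450 pairs and a 95th percentile of 2 (permutation p = 0.0175). WASF1 and SLC16A10 start at 110099819 and 111087503, just inside the limit of 1 Mb, so the p-value depends on that limit. The other pairs adjoin: GAS2 ends at 22813055 and SVIP starts at 22813799, and ZNRF2P1 ends at 32753744 and ENSG00000273014 starts at 32758882. After the length and GC correction 1 member of each pair no longer passed (SLC16A10 0.0535, SVIP 0.0977, ZNRF2P1 0.0751), with log2 fold changes of 1.73, 1.58 and 3.31 (SE 0.21, 0.25 and 0.46) against 1.95, 1.86 and 2.998 before (SE 0.27, 0.24 and 0.32), and the other members passed. At least 1 member of each did not pass without CfzR replicate 1 (SLC16A10 0.224, SVIP 0.159, ZNRF2P1 0.171) or without CfzR replicate 2 (0.0875, 0.0875 and 0.0822).

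The rise of genes around ABCB1 was set against reads shared between paralogues and a length and GC trend. Shared reads of ABCB1 and ABCB4 would leave the other genes of the window in place, but their median log2 fold change was 1.85. The level of ABCB4 itself stays open: its exact 50-base words shared with ABCB1 (1.87%) would account for an estimated 11.2% of its FPKM in a CfzR library, and aligned reads with mismatches would add to it. The trend is excluded as the whole cause, since the window's median was 2.84 after the correction against 2.69 before. Gain of DNA copies or altered regulation of the segment may underlie the pattern as a hypothesis, and neither was tested, since DNA was not measured.

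The lower ribosomal protein transcripts of CfzR replicate 1 were set against a length and GC trend and against resistance. After the correction, 77.0% of the median difference between the CfzR libraries remained (-0.48 before and -0.37 after). The correction used the longest annotated transcript, which need not be the one sequenced. It therefore cannot decide whether such a trend is the whole cause. If resistance were the cause, both CfzR libraries should show it, but the difference from WT in replicate 2 was 17.6% of that in replicate 1. Yet replicate 2 still lay further from WT (-0.10) than the WT libraries from each other (-0.04). The list turned positive under quantile normalization (camera adjusted p = 0.823). The FPKM sum was 673265 in CfzR replicate 1 against 877849 to 955284 in the other libraries, while medians lay between 7.50 and 7.75. A difference in the spread of values of that library was not tested as a cause. Resistance and a difference of that library cannot be told apart here.

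The loss of S100A4 and CST3 with the gain of SLAMF7 was set against a different myeloma line as the source of the CfzR libraries. The same leading immunoglobulin constant genes, IGKC, IGLC1, IGHA2 and IGHA1, came in the same order in 4 of 4 libraries. This argues against a line with other leading immunoglobulin genes. A line with the same leading genes would give the same result, so it is not excluded. The fitted length and GC trend is also too small to be the whole cause, as the 3 genes kept at least 96.5% of their log2 fold change. Selection of a subclone with these levels may underlie the pattern as a hypothesis, and it was not tested.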
